A study of Homo sapiens with 30 samples.

How the data were processed

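RNA sequencing of A549 cells, an established human lung adenocarcinoma line, was analysed in 30 libraries that form 10 groups of 3. The groups combine a knockout of RSRP1 (KOA in the labels) or the wild type (WTA), a magnetic exposure labelled 2 H (EX) or no exposure (NE), and the label parts iR and D3, whose meaning is not given in the sources used here. They are kept as names. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, enriched with oligo(dT) and primed with random hexamers before paired-end sequencing. The submitters' processing notes name fastp, HISAT2, HTSeq and the genome build GRCh38, with no versions. The annotation, the strand setting, the gene lengths and any filter are not given in the sources used here, so reads of overlapping sense and antisense genes cannot be told apart and near-identical copies such as HSPA1A and HSPA1B may have exchanged reads.

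The authors' deposited table holds 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each of 26,801 genes and library. Its columns were assigned to samples by their names, and 6 further columns of values matched no sample and were not used. FPKM removes depth and gene length within a library but not differences in composition: where a few genes gain or lose a large share of the reads, all other genes shift the opposite way. The steps between low values showed what 1 read was worth in each library, and for 26,800 of the 26,801 genes every value came out as a whole number of reads within a tolerance of 0.01. The recovered totals ran from 33,696,200 to 37,951,389 reads per library, a ratio of 1.126, so depth was close to even. Replicates were not copies of one library: over 14,828 genes the median squared difference between 2 replicates was 2.41 to 11.2 times what counting reads alone would give, over the 30 pairs of replicates. An FPKM of 0 is described as listed at 0, and no fold is given against a group at 0.

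Values were tested as log2(FPKM + 1), a pseudocount of 1, over the 12,086 genes with at least 1 FPKM in at least 3 libraries, of which 11,150 are protein-coding. All 10 groups were fitted in one linear model with limma 3.58.1 (R 4.3.3, moderated test with a mean-variance trend, 20 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg within each comparison, two-sided, with a threshold of 0.05. A log2 difference is on the log2(FPKM + 1) scale and understates the change of genes with low values. There were 15 comparisons: exposure in each of 5 backgrounds, genotype with and without D3 in unexposed iR libraries, D3 in each genotype, iR in the knockout, and 5 interactions that test whether an exposure effect differs between backgrounds. The labels do not say that the 3 samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical.

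The groups, the tests, the 25 gene lists, the rule for naming genes and the alternatives, except those said below to be added, were fixed before the data were examined. Of 784 list names, 755 were found by symbol, 15 through an NCBI identifier or synonym (13 of them mitochondrial genes, matched only after the data were seen) and 14 were not matched. For the 22 lists with at least 5 tested members, limma's camera set each list against all other genes with a preset correlation of 0.01, adjusted over 330 tests, and was repeated with a correlation estimated from each list. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. Lists share members, so their results are not separate. CCN1 and CCN2 are in the secreted, immediate early and matrix lists. CXCL1, CXCL2, CXCL3, CXCL8, CCL20, IL6, IL1A and IL1B are in both the secreted and the NF-kB lists. RSRP1 is named in every comparison. Other genes were named where they passed the threshold, reached 2 FPKM in 1 group and had all 3 libraries of one group above all 3 of the other (10 percent of genes do so by chance). The 10 largest rises and 10 largest falls were taken, or 5 of each for interactions. For each list past its test or with at least 3 members past, up to 4 members with the largest absolute difference were added, without the requirement on separate libraries. Clone and locus names, XIST and Y-linked genes were not named. CIRBP and RBM3 were chosen after their values were seen, and a gene named under one exposure background may be given in the others. Gene positions are from the RefSeq annotation of GRCh38.p14, in which 25,764 of the 26,801 gene identifiers were found.

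The fit was tested on simulated data: reads were drawn around each gene's mean over all 30 libraries, with the same fixed dispersion for every gene. In 1 group, 50 genes each were changed by 1.25, 1.5, 2 and 4 times. Real differences between groups and the real spread of each gene were not simulated, so the false calls below belong to a simpler setting than these data. For exposure in KOA, over 11,486 genes, 23, 46, 49 and 49 were recovered among 176 calls, 9 of them false. For genotype in iR, over 11,498 genes, 18, 47, 49 and 49 were recovered among 171 calls, 8 of them false. For the interaction of exposure and genotype in iR, 6, 39, 48 and 49 were recovered among 153 calls, 11 of them false. The recovery of reads gave exact reads for 100.0 percent of 3975 simulated genes.

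The alternatives were a pseudocount of 0.1, no filter, a filter of mean FPKM at least 5, median-of-ratios scaling, quantile normalization, a fit of the compared groups only, the replicate number as a block, each library left out in turn, and a floor of 1 on the absolute log2 difference. Set tests were also run with fry. Added after seeing the data was limma's voom on the recovered reads. Figures were drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. Wild-type cells without iR were not analysed here.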

Results

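Polyadenylated RNA of A549 cells, a human line used as a model of non-small-cell lung cancer, was sequenced in 30 libraries from 10 groups of 3. The series title places RSRP1, an arginine- and serine-rich protein, and secreted signals between a magnetic field and the restraint of these cells. The groups pair a magnetic exposure labelled 2 H with no exposure in 5 backgrounds: the RSRP1 knockout (KOA), the knockout with the label iR (iR_KOA), the same with the label D3 (iR_KOA_D3), and the corresponding wild-type backgrounds iR_WTA and iR_WTA_D3. Totals recovered from the values were 33,696,200 to 37,951,389 reads per library. Across genes, which are not independent replicates, libraries of one group correlated at 0.9899 to 0.998 and libraries of different groups at 0.9249 to 0.9931. The first principal component held 58 percent of the variance and separated the 2 genotypes.

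RSRP1 (chromosome 1, 25242249 to 25338254, NCBI gene 57035) was low in every library labelled as knockout and high in every library labelled as wild type. The 18 knockout libraries held 2.09 to 7.95 FPKM and the 12 wild-type libraries 37.4 to 63.4 FPKM. In unexposed cells RSRP1 was lower in the knockout by a log2 difference of −2.53 ± 0.059 (SE, n = 3 and 3) in iR (adjusted p = 3.83e-22) and by −2.48 in iR with D3 (adjusted p = 3.9e-22). The part of the gene that was removed is not given in the sources used here, and transcript remained in the knockout: 2.43 ± 0.29 FPKM (SD, n = 3) in unexposed KOA and 7.68 ± 0.25 in unexposed iR_KOA, a rise of 1.34 (adjusted p = 6.1e-15). With D3 it fell by 0.33 on the log2 scale in the wild type (adjusted p = 5.28e-05) and by 0.28 in the knockout (adjusted p = 0.00026).

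Exposure raised RSRP1 in both wild-type backgrounds, from 49.0 ± 0.77 to 62.9 ± 0.82 FPKM in iR_WTA (log2 difference 0.35, adjusted p = 5.67e-05) and from 38.9 ± 2.5 to 55.6 ± 3.7 FPKM in iR_WTA_D3 (0.51, adjusted p = 2.01e-07). RSRP1 fell in iR_KOA, from 7.68 ± 0.25 to 6.30 ± 0.52 FPKM (−0.25, adjusted p = 0.00185). The differences of −0.11 in KOA (adjusted p = 0.126) and 0.13 in iR_KOA_D3 (adjusted p = 0.0648) did not pass. The exposure effect differed between genotypes in iR (knockout minus wild type −0.61 ± 0.083, adjusted p = 0.000197) and in iR with D3 (−0.37, adjusted p = 0.0139). It also differed between iR_KOA_D3 and iR_KOA (0.39, adjusted p = 0.00824), whereas the differences iR_KOA minus KOA (−0.14, adjusted p = 0.424) and iR_WTA_D3 minus iR_WTA (0.15, adjusted p = 0.403) did not pass. The value in KOA passed without KOA_NE replicate 1 (−0.18), and the value in iR_KOA_D3 passed without iR_KOA_D3_EX replicate 2 (0.17) and under both other scalings (0.16 with median-of-ratios scaling, 0.17 with quantile normalization). The difference of the exposure effect between genotypes in iR with D3 did not pass when only the 4 compared groups were fitted.

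**Figure D1:**
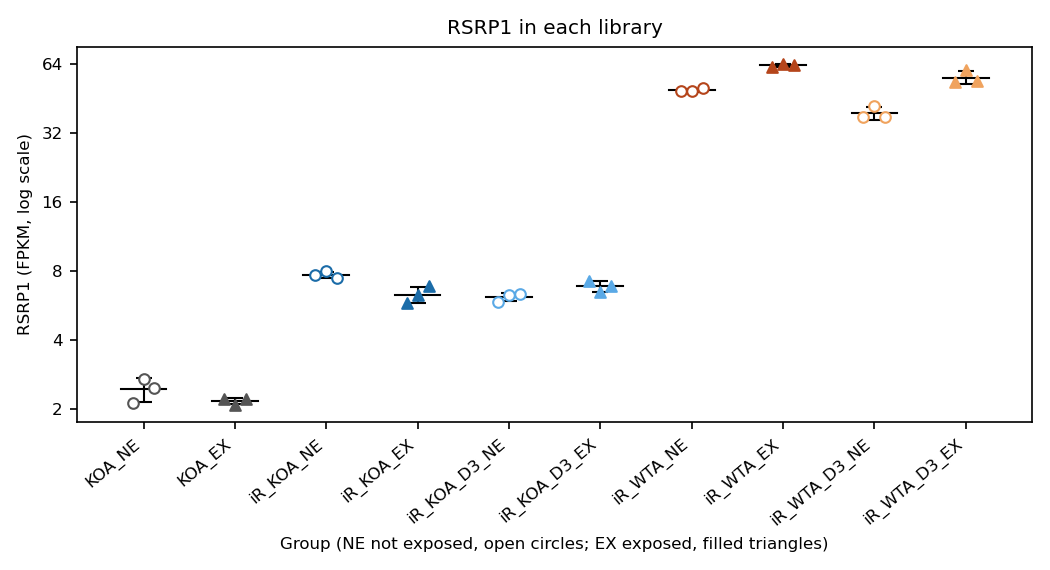
RSRP1 in FPKM on a log axis, one point per library, for the 5 backgrounds without exposure (open circles) and with exposure (filled triangles); bars are the mean ± SD of 3 libraries. The knockout libraries lie between 2.09 and 7.95 FPKM and the wild-type libraries between 37.4 and 63.4 FPKM, with exposed above unexposed in both wild-type backgrounds.

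In the knockout without iR (KOA), exposure raised the inducible chaperones most. HSPA1B, an inducible 70 kDa heat shock protein (chromosome 6, 31827738 to 31830254, NCBI gene 3304), rose from 12.9 ± 0.33 to 435 ± 56 FPKM (SD, n = 3 each), a log2 difference of 4.97 ± 0.16 (SE, adjusted p = 3.83e-18). HSPA6, a strictly inducible member of the same family (chromosome 1, 161524540 to 161526894, NCBI gene 3310), rose from 0.0353 ± 0.02 to 85.5 ± 15 FPKM (6.37 ± 0.16). The co-chaperones DNAJB4 (2.75), BAG3 (2.67) and HSPH1 (2.55) rose with them, as did DEDD2 (2.65), a death-effector-domain protein. CCN1 (2.92 ± 0.10), CCN2 (2.60 ± 0.07; chromosome 6, 131948176 to 131951372, NCBI gene 1490) and AMOTL2 (2.57 ± 0.08), known targets of the YAP coactivator, were also among the 10 largest rises. The largest falls were those of the nuclear receptor corepressor NRIP1, from 21.8 ± 0.51 to 8.32 ± 0.12 FPKM (−1.29), the calcium/calmodulin-dependent kinase kinase CAMKK1 (−1.26), GPCPD1 (−1.16), KLF11 (−1.08) and AXIN2, a feedback inhibitor of Wnt signalling (−1.06).

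Of 28 heat shock genes measured in KOA 25 rose and 0 fell, or 25 and 1 adjusted over the list alone (camera adjusted p = 6.03e-29, and adjusted p = 0.0272 with an estimated correlation). Of 38 secreted cytokine and senescence-associated genes 18 rose and 2 fell, or 19 and 3 adjusted over the list alone (camera adjusted p = 7.12e-07, and adjusted p = 0.00435 with an estimated correlation). Those that rose included CCN1 and CCN2, given above with larger rises, the chemokine CXCL8 (0.99) and the macrophage growth factor CSF1 (0.95). Of 21 NF-kB targets 12 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000716, and adjusted p = 0.0291 with an estimated correlation). Examples were CXCL2 (0.86) and the apoptosis inhibitor BIRC3 (0.79). Other list calls were lost with an estimated correlation. Of 42 genes of the unfolded protein and integrated stress responses 29 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 1.29e-08, and adjusted p = 0.25 with an estimated correlation). They included HERPUD1 of endoplasmic-reticulum-associated degradation (2.23) and DDIT3, which encodes the stress transcription factor CHOP (1.97). Of 27 immediate early genes 15 rose and 6 fell, or 16 and 6 adjusted over the list alone (camera adjusted p = 4.78e-06, and adjusted p = 0.0585 with an estimated correlation). Besides CCN1 and CCN2, which are also in this list, named members were the kinase phosphatases DUSP1 (1.59) and DUSP5 (1.38). Of 38 S-phase genes 31 fell and 1 rose, or 32 and 1 adjusted over the list alone (camera adjusted p = 4.96e-09, and adjusted p = 0.0935 with an estimated correlation). Among these were E2F2 (−1.03) and the primase subunit PRIM1 (−0.68). Of 35 G2/M genes 19 fell and 3 rose, or 20 and 3 adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.415 with an estimated correlation), with the kinesin KIF2C (−0.55) lower and CKS2 (0.59) higher.

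Of the 13 mitochondrially encoded genes 8 fell in KOA, also 8 adjusted over the list alone (camera adjusted p = 0.00631, and adjusted p = 0.484 with an estimated correlation), and the call ended under quantile normalization. ND1, a subunit of respiratory complex I, fell by 0.64 on the log2 scale. The share of all FPKM held by mitochondrially encoded genes was 24.4 ± 1 percent (SD, n = 3) with exposure and 28.4 ± 1.3 percent without. Of 43 genes of epithelial-mesenchymal transition and extracellular matrix 12 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.257 with an estimated correlation). The 12 hold CCN1, CCN2, the tight-junction gene CLDN1 (0.94) and the matrix glycoprotein THBS1 (0.78). The splicing list had no shift as a set (13 of 45 rose and 12 fell, also adjusted over the list alone; camera adjusted p = 0.679), yet its member CLK1, a kinase of SR proteins, rose (1.89) and SRSF6 fell (−0.54). Past the test in KOA were 5020 of 12,086 genes, 2272 higher and 2748 lower, and 109 had an absolute log2 difference of at least 1, of which 102 were higher.

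In the wild type with iR (iR_WTA), 1 of 2 backgrounds with intact RSRP1, the same chaperones were among the largest rises. HSPA1B rose from 10.8 ± 0.83 to 253 ± 45 FPKM (log2 difference 4.42 ± 0.16, SE, adjusted p = 1.47e-16) and HSPA6 from 0.0192 ± 0.018 to 19.0 ± 2.4 FPKM (4.29). HERPUD1 (chromosome 16, 56932142 to 56944864, NCBI gene 9709) rose from 15.6 ± 1.2 to 109 ± 37 FPKM (2.67 ± 0.15), followed by DEDD2 (2.16), the co-chaperone DNAJB1 (2.05) and DDIT3 (2.04; chromosome 12, 57516588 to 57520517, NCBI gene 1649). BHLHE40, a transcriptional repressor of the clock, rose from 45.3 ± 0.68 to 97.1 ± 2 FPKM (1.08 ± 0.03). The largest falls were CAMKK1 (−1.12), the splicing factor SRSF5 from 80.5 ± 5.3 to 40.9 ± 1.6 FPKM (−0.96), CABYR (−0.81), IGFBP1, which binds insulin-like growth factors (−0.79), and the ubiquitin ligase RNF126 (−0.79).

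Heat shock genes rose in 24 of 28 cases and fell in 1 in iR_WTA, the same adjusted over the list alone (camera adjusted p = 1.57e-34, and adjusted p = 0.0198 with an estimated correlation). Of the 42 unfolded protein and integrated stress response genes 28 rose and 1 fell, or 30 and 1 adjusted over the list alone (camera adjusted p = 1.15e-22, and adjusted p = 0.0475 with an estimated correlation). Examples were DNAJB9 (1.98) and HSPA5, the main chaperone of the endoplasmic reticulum (1.29; chromosome 9, 125234853 to 125241343, NCBI gene 3309). Of the 27 immediate early genes 20 rose and 1 fell, or 20 and 2 adjusted over the list alone (camera adjusted p = 4.36e-15, and adjusted p = 0.00435 with an estimated correlation). They included JUNB (1.02) and JUN (0.98). Of the 30 cholesterol synthesis genes 18 rose and 1 fell, or 21 and 2 adjusted over the list alone (camera adjusted p = 3.08e-09, and adjusted p = 0.00435 with an estimated correlation). One of them was the sterol carrier STARD4 (0.68). Lost with an estimated correlation was the fall of 31 of 38 S-phase genes, 33 adjusted over the list alone (camera adjusted p = 9.27e-11, and adjusted p = 0.0669 with an estimated correlation). The same held for 17 G2/M genes that fell against 1 that rose, or 19 and 3 adjusted over the list alone (camera adjusted p = 0.00282, and adjusted p = 0.459 with an estimated correlation). Of the secreted factors 11 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.00515, and adjusted p = 0.0662 with an estimated correlation). Among these were the cytokines LIF (0.91) and IL11 (0.73). Of the matrix list 12 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.00197, and adjusted p = 0.152 with an estimated correlation). The threshold was passed by 3462 genes, 1381 higher and 2081 lower (1539 and 1546 with quantile normalization), and 32 of the 33 genes with an absolute log2 difference of at least 1 were higher.

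In iR_KOA, HSPA1B rose from 11.1 ± 0.49 to 216 ± 67 FPKM (log2 difference 4.12, adjusted p = 1.58e-15), HSPA6 by 3.41 and HERPUD1 by 2.31, with DNAJB4 (2.09), HSPH1 (1.87) and BAG3 (1.64) next to them. LIF, a cytokine, rose from 15.3 ± 1.5 to 30.6 ± 2.2 FPKM (0.96). CAMKK1 and AXIN2 fell by 1.03 each on the log2 scale, SRSF5 by 0.98, and CIRBP, a cold-inducible RNA-binding protein, by 0.77. Heat shock genes rose in 24 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 1.1e-29, and adjusted p = 0.0272 with an estimated correlation). Immediate early genes rose in 16 cases and fell in 4, or 16 and 5 adjusted over the list alone (camera adjusted p = 7.88e-09, and adjusted p = 0.0249 with an estimated correlation), and secreted factors rose in 16 and fell in 4, or 17 and 4 adjusted over the list alone (camera adjusted p = 2.05e-05, and adjusted p = 0.0112 with an estimated correlation). The calls of unfolded protein response genes (26 rose, 1 fell; 28 and 1 adjusted over the list alone; adjusted p = 0.0786 with an estimated correlation), S-phase genes (33 fell, 1 rose, also adjusted over the list alone; adjusted p = 0.068) and G2/M genes (20 fell, 1 rose, also adjusted over the list alone; adjusted p = 0.362) were lost there. So were those of NF-kB targets (12 rose, 3 fell; adjusted p = 0.0633 with an estimated correlation) and cholesterol synthesis (11 rose, 5 fell; adjusted p = 0.0837). Ribosomal protein genes fell in 27 of 57 cases, 32 adjusted over the list alone (camera adjusted p = 6.15e-05, and adjusted p = 0.692 with an estimated correlation), and nuclear respiratory chain genes in 12 of 42, 12 adjusted over the list alone (camera adjusted p = 0.00282, and adjusted p = 0.688). The matrix list had a median of −0.03 and a mean of 0.10, and camera placed it upward (adjusted p = 0.0448, and adjusted p = 0.366 with an estimated correlation). Genes past the test numbered 4272, 1578 higher and 2694 lower, against 1862 and 1976 with median-of-ratios scaling, and 2131 when only the 2 groups were fitted.

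With D3, exposure of the knockout (iR_KOA_D3) raised HSPA1B from 13.4 ± 1.6 to 208 ± 30 FPKM (log2 difference 3.85, adjusted p = 2.32e-15), HERPUD1 from 27.9 ± 0.98 to 163 ± 10 FPKM (2.51) and the HSP90 co-chaperone CHORDC1 by 2.37. CCN2 rose by 1.59 and LIF by 0.95, while BMF, a pro-apoptotic BH3-only protein (chromosome 15, 40087890 to 40108879, NCBI gene 90427), fell from 3.04 ± 0.054 to 0.405 ± 0.06 FPKM (−1.52). RNF126 (−1.20), SRSF5 (−1.16), SLFN5 (−1.15) and SOCS3, an inhibitor of cytokine signalling (−1.09), fell too. Heat shock genes rose in 25 cases and fell in 0, also adjusted over the list alone (camera adjusted p = 2.04e-25, and adjusted p = 0.0363 with an estimated correlation). Unfolded protein response genes rose in 29 and fell in 2, or 30 and 2 adjusted over the list alone (camera adjusted p = 1.36e-11, and adjusted p = 0.164 with an estimated correlation), and S-phase genes fell in 30 and rose in 1, or 34 and 1 adjusted over the list alone (camera adjusted p = 1.54e-08, and adjusted p = 0.106). Of 36 p53 targets 14 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.00248, and adjusted p = 0.0633 with an estimated correlation). One example was the cell-cycle inhibitor CDKN1A (0.72). Of 36 hypoxia and glycolysis genes 15 fell and 3 rose, or 17 and 4 adjusted over the list alone (camera adjusted p = 0.0348, and adjusted p = 0.485 with an estimated correlation). A member was NDRG1 (−0.63). The cholesterol list had a median of −0.01 and a mean of 0.14, and camera placed it upward (12 rose, 4 fell; adjusted p = 0.0122, and adjusted p = 0.162 with an estimated correlation). One of these was INSIG1 (0.94). The call of the list ended under quantile normalization. Immediate early genes (14 rose, 4 fell; adjusted p = 0.068 with an estimated correlation) and secreted factors (13 rose, 6 fell; adjusted p = 0.109) passed with the preset correlation alone. Past the test were 5455 genes, 2093 higher and 3362 lower.

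In iR_WTA_D3, HSPA1B rose from 12.8 ± 0.36 to 257 ± 44 FPKM (log2 difference 4.21, adjusted p = 4.65e-16), HERPUD1 from 20.0 ± 1.1 to 162 ± 4 FPKM (2.96) and DNAJB9 from 9.51 ± 0.66 to 60.5 ± 9.1 FPKM (2.54). INSIG1, which retains sterol regulators in the endoplasmic reticulum, rose by 0.86. BMF fell from 3.33 ± 0.15 to 0.458 ± 0.12 FPKM (−1.57), the retinoic acid receptor RARB by 1.07 and the chemokines CCL2 and CXCL1 by 1.05 and 0.62 on the log2 scale. The list of secreted factors did not pass here, with 9 of 38 that rose and 7 that fell, also adjusted over the list alone (median −0.005, camera adjusted p = 0.288). Heat shock genes rose in 25 cases and fell in 1, or 26 and 1 adjusted over the list alone (camera adjusted p = 1.91e-29, and adjusted p = 0.0272 with an estimated correlation). Cholesterol synthesis genes rose in 18 and fell in 1, or 19 and 2 adjusted over the list alone (camera adjusted p = 6.57e-09, and adjusted p = 0.00435 with an estimated correlation). Of the p53 targets 16 rose and 5 fell, or 18 and 5 adjusted over the list alone (camera adjusted p = 0.000197, and adjusted p = 0.0272 with an estimated correlation). Examples were SESN2 (0.80), EDA2R (0.73) and CDKN1A (0.67). Lost with an estimated correlation were the calls of unfolded protein response genes (27 rose, 2 fell; 28 and 2 adjusted over the list alone; adjusted p = 0.134), S-phase genes (31 fell, 2 rose; 33 and 2 adjusted over the list alone; adjusted p = 0.14) and immediate early genes (16 rose, 4 fell; 18 and 5 adjusted over the list alone; adjusted p = 0.068). The threshold was passed by 5055 genes, 1852 higher and 3203 lower, against 2283 and 2478 with median-of-ratios scaling.

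No library was shared among the 5 exposure comparisons, but all used the same estimate of each gene's spread, so their calls are not independent. In all 5, 723 genes were higher and 951 lower. Independent lists of calls would give 0.899 and 7.78, a baseline that the shared spread makes too low. Across genes, which are not independent replicates, the log2 differences of any 2 backgrounds correlated at 0.657 to 0.805, and of the genes past the test in both, 96.4 to 99.6 percent moved the same way. The mean log2 difference of FPKM + 1 over the 5 backgrounds was 4.31 for HSPA1B, 3.95 for HSPA6, 2.53 for HERPUD1, 2.15 for HSPH1, 2.00 for DNAJB9 and 1.68 for DDIT3. For HSPA6, at 0.00789 to 0.0499 FPKM without exposure, the added 1 sets the size of this value. CAMKK1 (mean log2 difference −1.20), RNF126 (−0.99), BMF (−0.98), SRSF5 (−0.92), SLFN5 (−0.89) and E2F2 (−0.83) were lower in all 5. CIRBP (chromosome 19, 1269332 to 1274880, NCBI gene 1153) was lower in all 5 with a mean of −0.66, and RBM3, another cold-inducible RNA-binding protein, fell by 0.15 to 0.34 on the log2 scale. The fall of RBM3 in KOA did not pass with the compared groups only, nor without KOA_EX replicate 1 (−0.108) or 2 (−0.128) or KOA_NE replicate 2 (−0.145) or 3 (−0.122). HSPA1A, which is near-identical to HSPA1B, had a mean of 3.95, and the reads of both are uncertain.

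**Figure D2:**
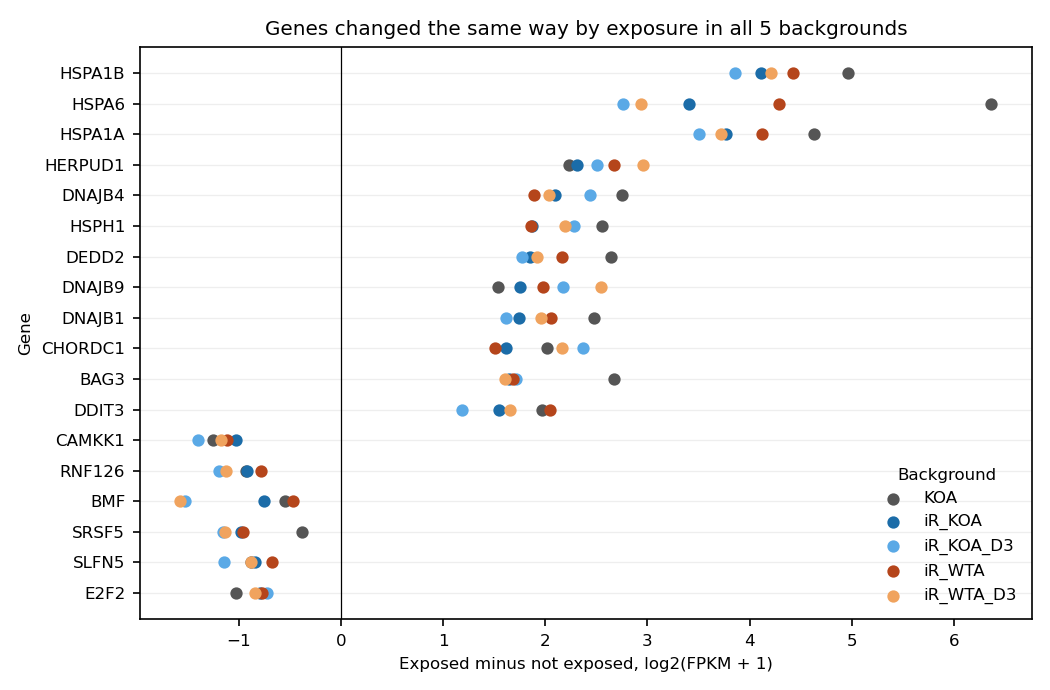
Log2 difference of FPKM + 1, exposed minus unexposed, for 12 genes with the largest mean rise and 6 with the largest mean fall among genes past the test in all 5 backgrounds. Each point is one background (3 against 3 libraries). HSPA1B lies between 3.85 and 4.97 and CAMKK1 between −1.40 and −1.03.

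For several lists the set test did not pass with exposure in any background. Among 38 interferon-stimulated genes more fell than rose: 5 and 2 in KOA (camera adjusted p = 0.366), 13 and 1 in iR_KOA (0.056), 15 and 1 in iR_KOA_D3 (0.115), 8 and 1 in iR_WTA (0.141) and 12 and 1 in iR_WTA_D3 (0.143). Adjusted over the list alone the counts were 5 and 1 in KOA and 7 and 1 in iR_WTA, and equal elsewhere. Splicing factors differed in balance: of 45, 13 rose and 12 fell in KOA (0.679), 8 and 9 in iR_KOA (0.743), 17 and 12 in iR_KOA_D3 (0.0774), 5 and 10 in iR_WTA (0.808) and 13 and 11 in iR_WTA_D3 (0.115). Of 13 replication-dependent histones 4 rose and 0 fell in KOA (0.0774), 1 fell in iR_KOA (0.929), 2 rose and 1 fell in iR_KOA_D3 (0.149), and 1 rose in iR_WTA (0.549) and in iR_WTA_D3 (0.644). NRF2 targets, of which 37 were measured, fell more often than they rose, in 12 against 2 in KOA (0.0762), 8 against 4 in iR_KOA (0.667), 13 against 5 in iR_KOA_D3 (0.855), 7 against 4 in iR_WTA (0.469) and 10 against 3 in iR_WTA_D3 (0.708).

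Some lists passed in only part of the 5 backgrounds. NF-kB targets, higher in KOA and iR_KOA, rose in 6 of 21 cases and fell in 3 in iR_WTA (camera adjusted p = 0.193), 6 and 9 in iR_KOA_D3 (0.886) and 4 and 6 in iR_WTA_D3 (0.656). The p53 targets rose in 10 of 36 cases and fell in 7 in both KOA (0.193) and iR_WTA (0.116), and 9 and 7 in iR_KOA (0.0634). With D3, G2/M genes rose in 5 of 35 cases and fell in 9 in the knockout (0.808), and 5 and 11 in the wild type (0.87). There the matrix list rose in 9 of 43 cases and fell in 7 in the knockout (0.363), and 12 and 7 in the wild type (0.144). Hypoxia genes rose in 7 of 36 cases and fell in 7 in KOA (0.754) and in iR_WTA (0.877), with 4 and 7 in iR_KOA (0.508) and 3 and 12 in iR_WTA_D3 (0.174). Cholesterol synthesis genes rose in 9 of 30 cases and fell in 3 in KOA (0.141). Mitochondrially encoded genes rose in 2 of 13 cases in iR_KOA (0.101), fell in 3 in iR_KOA_D3 (0.885) and in 1 in iR_WTA (0.936), and 1 rose and 3 fell in iR_WTA_D3 (0.747). Of 42 nuclear respiratory chain genes 2 rose and 3 fell in KOA (0.985), 2 and 2 in iR_KOA_D3 (0.2), 0 and 2 in iR_WTA (0.312) and 0 and 4 in iR_WTA_D3 (0.72; limma). Of 57 ribosomal protein genes 1 rose in KOA (0.877), 0 changed in iR_KOA_D3 (0.289), and 2 fell in iR_WTA (0.098) and 3 in iR_WTA_D3 (0.631; limma). Adjusted over the list alone, 0 ribosomal protein genes passed in these 4 backgrounds (limma).

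Counts of 4 more lists, which passed with exposure in no background, are given for iR_WTA. Of 26 iron-handling and ferroptosis genes 4 rose and 4 fell (camera adjusted p = 0.821), and of 15 clock and cryptochrome genes 4 rose and 3 fell, or 4 and 4 adjusted over the list alone (0.216). Of 10 alveolar and lung adenocarcinoma markers 1 rose (0.292), and of the 6 genomic neighbours of RSRP1 1 fell, or 0 adjusted over the list alone (0.683). Markers of other cell types were scarce in this line, and none of these lists was large enough for a set test. Of 12 fibroblast markers 3 were measured and 1 rose, and of 11 endothelial markers 2 were measured and 0 changed. Of 22 leukocyte and macrophage markers only 13 were found among the deposited genes, of which 3 were measured and 1 fell. These limma counts were equal adjusted over the list alone. All 3 leukocyte and macrophage markers fell in iR_KOA_D3 and 2 in iR_WTA_D3. The count of 330 list tests over all 15 comparisons past the threshold was 136 with the preset correlation and 38 with an estimated one.

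**Figure D3:**
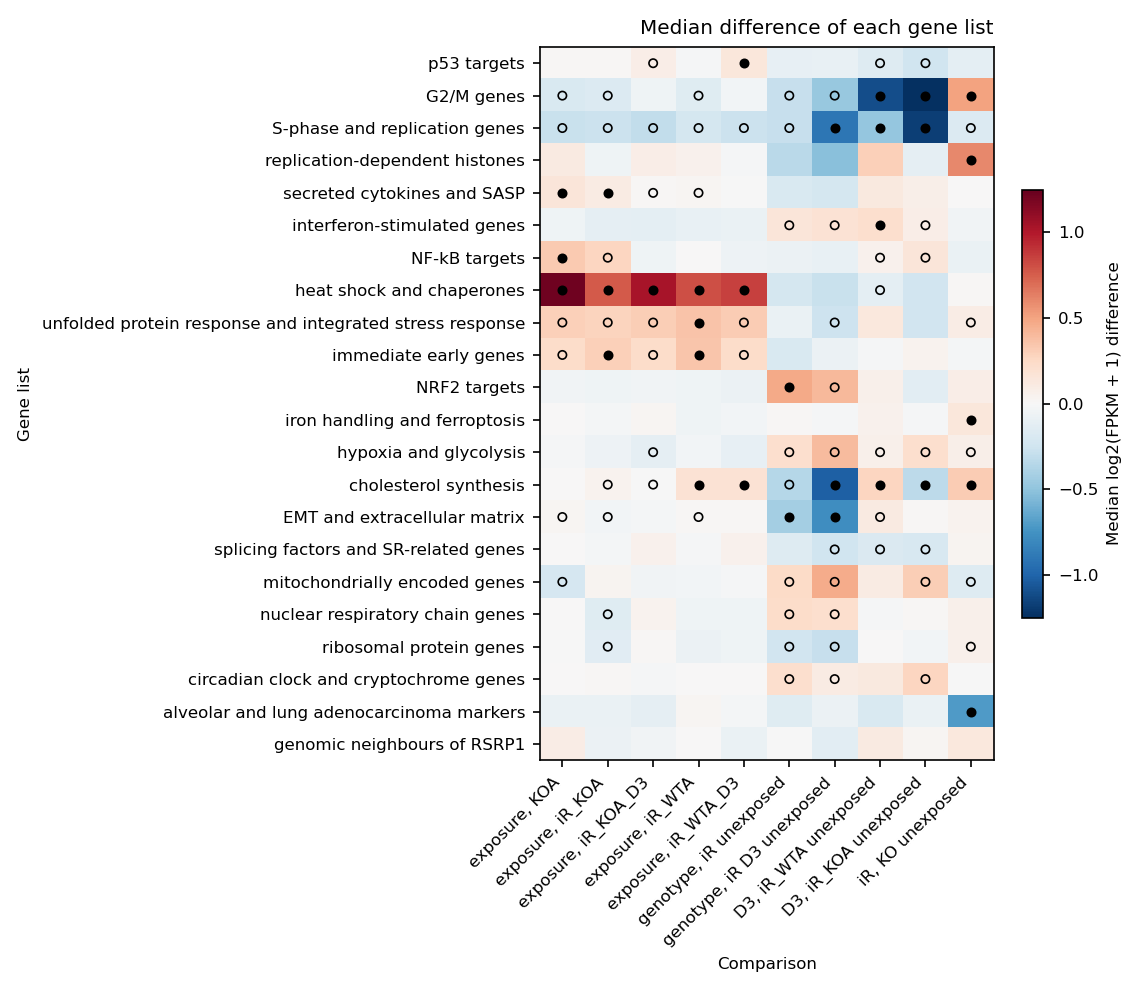
Median log2 difference (colour) of 22 gene lists in the 10 pairwise comparisons, with an open circle where the camera adjusted p was under 0.05 and a filled circle where it also was with an estimated correlation. Heat shock genes carry a filled circle in all 5 exposure comparisons (medians 0.765 to 1.212), and G2/M genes have medians of −1.11 and −1.264 with D3.

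Genotypes were compared between unexposed iR_KOA and iR_WTA. OLFML3, a secreted glycoprotein (chromosome 1, 113979474 to 113982253, NCBI gene 56944), was at 0.71 ± 0.22 FPKM in the knockout and 78.0 ± 2.5 FPKM in the wild type (SD, n = 3 each; log2 difference −5.54 ± 0.09, SE). The glutamate transporter SLC1A3 (−4.68 ± 0.04; chromosome 5, 36596588 to 36688334, NCBI gene 6507), the keratin KRT19 (−4.00), the annexin ANXA10 (−3.98), the gelatinase MMP2 (−3.64), the proteoglycan VCAN (−3.64) and the cytokine IL11 (−3.29) were lower, and the collagen COL11A1 was listed at 0 in the knockout and at 13.6 ± 0.52 FPKM in the wild type. Higher in the knockout were CPLX2, a regulator of vesicle fusion, at 454 ± 13 against 35.9 ± 1.8 FPKM (3.62 ± 0.05; chromosome 5, 175796533 to 175884021, NCBI gene 10814), the mucin MUC5B (3.17), the SNARE protein VAMP8 (3.15), the fatty acid transporter SLC27A2 (3.09) and the neurofilament NEFL (3.19). MAGEA6 was also higher (3.39), though its reads may be shared with near-identical family members.

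Lists past the test with an estimated correlation were NRF2 targets and the matrix list. Of 37 NRF2 targets 30 were higher in iR_KOA and 3 lower, also adjusted over the list alone (camera adjusted p = 3.9e-12, and adjusted p = 0.0278 with an estimated correlation). They included the glutathione peroxidase GPX2 at 444 ± 21 against 88.6 ± 2.7 FPKM (2.31; chromosome 14, 64939158 to 64942745, NCBI gene 2877), the heme oxygenase HMOX1 (1.79) and AKR1C1 (1.62). Of 43 matrix genes 32 were lower and 8 higher, also adjusted over the list alone (camera adjusted p = 6.22e-07, and adjusted p = 0.0278 with an estimated correlation). Named members were the integrin ITGB3 (−2.88), SPOCK1 (−2.41) and COL5A1 (−2.12). Cholesterol synthesis genes were lower in 22 cases and higher in 3, also adjusted over the list alone (camera adjusted p = 0.000625, and adjusted p = 0.0602 with an estimated correlation). S-phase genes were lower in 30 and higher in 4, or 31 and 4 adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.37 with an estimated correlation), and G2/M genes lower in 26 and higher in 3 by both adjustments (adjusted p = 0.387 with an estimated correlation). One example was KIF20A (−1.04; chromosome 5, 138179112 to 138187723, NCBI gene 10112). Hypoxia genes were higher in 21 and lower in 8, also adjusted over the list alone (adjusted p = 0.303 with an estimated correlation). A member was the carbonic anhydrase CA12 (1.88). Nuclear respiratory chain genes were higher in 26 and lower in 4 (adjusted p = 0.622 with an estimated correlation), and ribosomal protein genes lower in 36 and higher in 4 (adjusted p = 0.73), the same adjusted over the list alone. Interferon-stimulated genes were higher in 19 and lower in 7, also adjusted over the list alone (adjusted p = 0.17 with an estimated correlation), with IFIT1 higher (1.13) and GBP1 lower (−1.03). Of the few markers of other cell types measured, 2 of 3 fibroblast markers were lower and 1 higher, and 3 of 3 leukocyte and macrophage markers were higher. Mitochondrially encoded genes (10 higher, 1 lower; adjusted p = 0.549 with an estimated correlation) and clock genes (10 higher, 3 lower; adjusted p = 0.162) lost their calls under quantile normalization, and clock genes under median-of-ratios scaling too. The share of FPKM held by mitochondrially encoded genes was 24.6 ± 0.31 percent in iR_KOA and 21.1 ± 1.1 percent in iR_WTA. Genes past the test numbered 7895, 3375 higher and 4520 lower, and 600 with an absolute log2 difference of at least 1 (334 higher, 266 lower).

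With D3 the unexposed genotypes differed again in OLFML3 (1.09 ± 0.082 against 94.6 ± 2.1 FPKM, log2 difference −5.51), SLC1A3 (−4.44), KRT19 (−4.42), MMP2 (−4.21) and the growth factor MDK (−3.42), with COL11A1 listed at 0 in the knockout and at 28.6 ± 0.89 FPKM in the wild type. CPLX2 (3.58), the fibrinogen chain FGG at 40.9 ± 2.4 against 2.51 ± 0.15 FPKM (3.58), MUC5B (3.52) and the antiprotease SLPI (3.26) were higher. The carbonic anhydrase CA9 (chromosome 9, 35673928 to 35681159, NCBI gene 768) was at 15.6 ± 2.6 FPKM in the knockout and 1.72 ± 0.63 in the wild type (2.62). Of the 30 cholesterol synthesis genes 28 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 1.28e-10, and adjusted p = 0.00435 with an estimated correlation). One of them was the synthase HMGCS1 (−1.53). Of 38 S-phase genes 36 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 3.9e-13, and adjusted p = 0.044 with an estimated correlation). Among these were CDT1, which licenses replication origins (−1.42), and UHRF1 (−1.41). Matrix genes were lower in 33 cases and higher in 5, also adjusted over the list alone (camera adjusted p = 1.54e-06, and adjusted p = 0.0312 with an estimated correlation), with COL4A1 lower (−2.56) and fibronectin FN1 higher, at 523 ± 18 against 90.6 ± 4 FPKM (2.52). NRF2 targets were higher in 28 and lower in 5, or 28 and 6 adjusted over the list alone (camera adjusted p = 1.46e-08, and adjusted p = 0.0662 with an estimated correlation). Genes of the unfolded protein and integrated stress responses were lower in 24 and higher in 5, or 25 and 5 adjusted over the list alone (camera adjusted p = 0.0112, and adjusted p = 0.669 with an estimated correlation). Examples were TRIB3 (−1.69), the glycoprotein hormone STC2 (−1.43; chromosome 5, 173314723 to 173328414, NCBI gene 8614) and ATF4 (−1.18). G2/M genes were lower in 31 and higher in 3 (adjusted p = 0.287 with an estimated correlation), and hypoxia genes higher in 24 and lower in 8 (adjusted p = 0.101). Mitochondrially encoded genes, whose call ended under quantile normalization, were higher in 10 of 13 and lower in 0, also adjusted over the list alone (camera adjusted p = 0.000225, and adjusted p = 0.323 with an estimated correlation). They held 29.4 ± 1.2 percent of FPKM in the knockout and 22.9 ± 0.43 percent in the wild type. Nuclear respiratory chain genes (25 higher, 5 lower; adjusted p = 0.504 with an estimated correlation), ribosomal protein genes (42 lower, 3 higher; 0.748) and clock genes (7 higher, 1 lower; 0.0813) lost their calls there. So did interferon-stimulated genes (19 higher, 9 lower; 0.17) and splicing factors (31 lower, 6 higher; 0.451), which also did not pass under either other scaling. Of 3 fibroblast markers 2 were lower and 1 higher, and of 3 leukocyte and macrophage markers 2 were higher and 1 lower. Past the test were 8352 genes, 3002 higher and 5350 lower, against 3781 and 4151 with median-of-ratios scaling; the median of all genes was −0.11 in the FPKM values and −0.02 after that scaling.

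The shifts of chromosomes were examined only after the differences were seen, whereas a test placing 2-fold genes in windows of 40 neighbouring genes was written before. Genes on chromosome 2 were higher in the knockout than other genes, with a median of 0.323 over 809 genes in iR and 0.259 with D3, or 0.401 and 0.389 relative to all other genes, where medians of permuted chromosomes reached 0.12 and 0.094. Relative medians also lay above the permuted ones on chromosomes X (0.222 and 0.226 over 382 genes), 15 (0.218 and 0.208) and 17 (0.171 and 0.178). Chromosomes 14 (−0.134 and −0.126) and 16 (−0.107 and −0.112) lay below the lowest permuted medians of −0.106 and −0.079. Of 301 windows of 40 neighbouring genes 26 lay outside the range of 100 permutations in iR, all above it, 17 on chromosome 2, 4 on chromosome X, 3 on chromosome 15 and 1 each on chromosomes 17 and 5. With D3 18 lay outside, 13 on chromosome 2 and 4 on chromosome X. The 4 windows of chromosome X span 276356 to 56995541, with medians of 0.527 to 0.713 in iR, and its other 6 windows had medians of −0.084 to 0.07. VAMP8, FN1 and the respiratory chain genes COX5B and ATP5MC3 lie on chromosome 2. CPLX2 lies in the chromosome 5 window above the range in iR (174724582 to 178885020, median 0.292). SLC27A2 lies in one of those on chromosome 15 (48878134 to 57291310, median 0.327). Both medians were far smaller than the differences of these 2 genes. In the D3 comparisons 0 windows lay outside the permuted range in either genotype, and for exposure 0 did in iR_WTA. Shifts also appeared within one genotype: 2 windows lay above the range in the iR comparison of the knockout and 3 below it for exposure in KOA. Chromosomes 5 (0.082), 18 (0.081), 13 (0.064) and 22 (−0.07) lay outside the permuted medians for iR, and chromosome 17 (−0.075) for exposure in KOA.

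**Figure D4:**
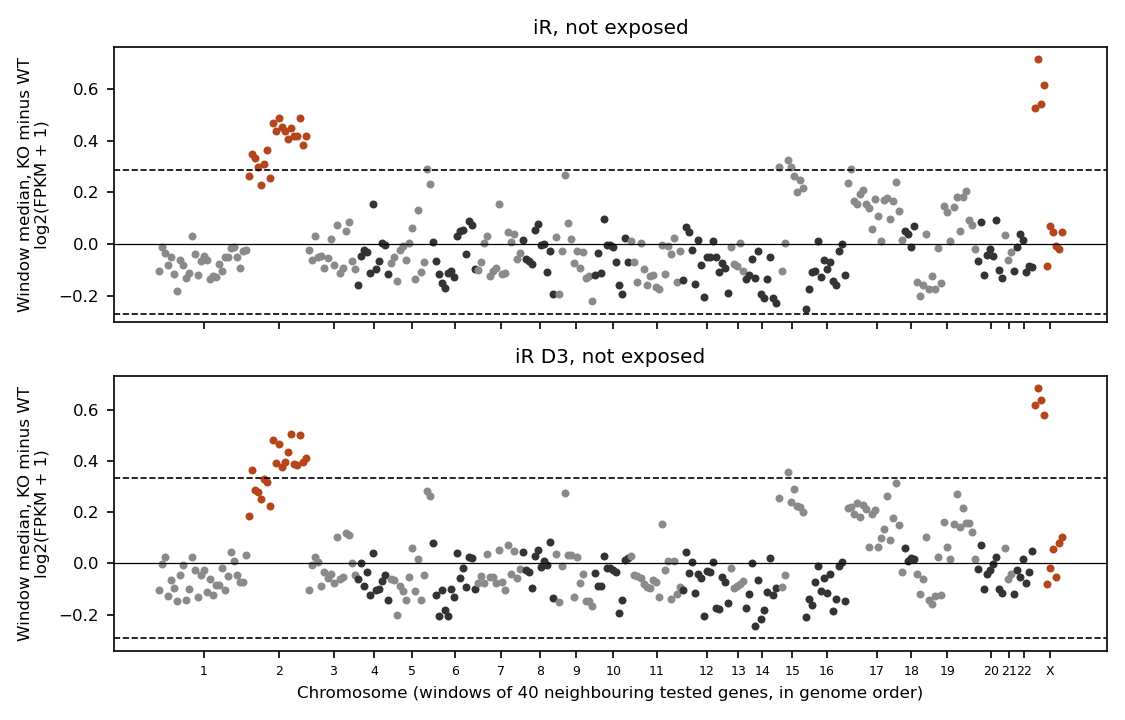
Median log2 difference, knockout minus wild type, of 301 windows of 40 neighbouring genes along the genome, relative to the median of all placed genes. The upper panel is unexposed iR and the lower panel unexposed iR with D3. Chromosomes 2 and X are in orange. Dashed lines mark the range of 100 permutations of genes (−0.269 to 0.285 in iR, −0.292 to 0.332 with D3). Of 26 windows above that range in iR, 17 are on chromosome 2 and 4 on chromosome X. With D3, 13 of 18 are on chromosome 2 and 4 on chromosome X.

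Comparing D3 with its absence in unexposed wild-type iR cells, all measured genes of the G2/M and S-phase lists were lower. Of 25 replication-dependent histones listed 13 were measured, of which 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.0648). The libraries were enriched for polyadenylated RNA, so these values may not reflect all histone transcripts. KIF20A, a mitotic kinesin, fell from 45 ± 0.79 to 15.6 ± 0.31 FPKM (SD, n = 3 each; log2 difference −1.47), cyclin B1 (CCNB1) from 159 ± 1.3 to 64.5 ± 2.9 FPKM (−1.29), and DLGAP5 (−1.45) and CDC20 (−1.32) fell as well. The lipopolysaccharide-binding protein LBP rose from 1.58 ± 0.25 to 6.88 ± 0.5 FPKM (1.61 ± 0.10, SE), BMF by 1.56, the desaturase SCD by 0.99 and E-cadherin (CDH1) from 19.8 ± 1.1 to 44.0 ± 1.3 FPKM (1.12). All 35 G2/M genes fell, also adjusted over the list alone (camera adjusted p = 1.57e-34, and adjusted p = 0.00435 with an estimated correlation), and all 38 S-phase genes fell, also adjusted over the list alone (camera adjusted p = 8.64e-19, and adjusted p = 0.021 with an estimated correlation). One of these was RRM2 of ribonucleotide reductase (−1.11). Cholesterol synthesis genes rose in 20 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 3.79e-07, and adjusted p = 0.0112 with an estimated correlation). One of them was LSS (0.65). Interferon-stimulated genes rose in 19 and fell in 2, or 20 and 3 adjusted over the list alone (camera adjusted p = 0.000848, and adjusted p = 0.0371 with an estimated correlation), with STAT2 (0.64) and IFITM3 (0.49) higher and OAS3 lower (−0.57). All 3 measured leukocyte and macrophage markers and 2 of 3 fibroblast markers rose too. Splicing factors fell in 28 of 45 and rose in 2, also adjusted over the list alone (camera adjusted p = 3.96e-05, and adjusted p = 0.101 with an estimated correlation), and p53 targets fell in 19 and rose in 1, or 19 and 2 adjusted over the list alone (camera adjusted p = 0.00395, and adjusted p = 0.068). Also lost with an estimated correlation were the calls of the matrix list (20 rose, 7 fell; adjusted p = 0.244), hypoxia genes (10 rose, 4 fell; adjusted p = 0.446), heat shock genes (13 fell, 2 rose; adjusted p = 0.706) and NF-kB targets (8 rose, 0 fell; adjusted p = 0.17), the last also under both other scalings. The threshold was passed by 5880 genes, 2697 higher and 3183 lower, with 82 at an absolute log2 difference of at least 1, of which 58 were lower.

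In the unexposed knockout replication genes fell with D3. RRM2 fell from 71.9 ± 3.6 to 21.4 ± 0.55 FPKM (log2 difference −1.70), with ORC6 of the origin recognition complex (−1.73), NCAPG of condensin (−1.59) and PRIM1 (−1.45). CA9 rose from 0.889 ± 0.17 to 15.6 ± 2.6 FPKM (3.12), FGG from 10.1 to 40.9 ± 2.4 FPKM (1.92), and complement C3 from 39.4 ± 2.5 to 118 ± 3.3 FPKM (1.56), next to PRG4 (1.91), ceruloplasmin (CP, 1.70) and SLPI (1.60). All 35 G2/M genes and all 38 S-phase genes fell, also adjusted over the list alone (camera adjusted p = 7.39e-29 and 1.11e-29, and adjusted p = 0.00912 and 0.00435 with an estimated correlation). Cholesterol synthesis genes fell in 27 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 2.93e-05, and adjusted p = 0.0272 with an estimated correlation). Among these were ACAT2 (−1.18) and FDPS (−0.87). Hypoxia genes rose in 22 and fell in 2, or 23 and 2 adjusted over the list alone (camera adjusted p = 2.3e-07, and adjusted p = 0.068 with an estimated correlation). Examples were ALDOC (1.05) and NDRG1 (0.94). Splicing factors fell in 29 and rose in 1, or 30 and 1 adjusted over the list alone (camera adjusted p = 0.000295, and adjusted p = 0.151 with an estimated correlation). Among these was LUC7L3 (−0.51). Mitochondrially encoded genes rose in 8 and fell in 0, also adjusted over the list alone (camera adjusted p = 0.000817, and adjusted p = 0.368 with an estimated correlation), a call that ended under quantile normalization, and NF-kB targets rose in 9 and fell in 2, or 10 and 2 adjusted over the list alone (adjusted p = 0.0633 with an estimated correlation). Clock genes (8 rose, 3 fell; adjusted p = 0.111 with an estimated correlation), interferon-stimulated genes (12 rose, 7 fell; 0.164) and p53 targets (21 fell, 3 rose; 0.215) passed with the preset correlation only and under neither other scaling. Of 3 leukocyte and macrophage markers 2 rose and 1 fell. Whether the D3 difference itself differs between genotypes was not tested. Genes past the test numbered 6485, 2315 higher and 4170 lower, against 3419 and 2930 with median-of-ratios scaling.

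Within the unexposed knockout, iR_KOA was compared with KOA. The gel-forming mucins MUC5AC (chromosome 11, 1157953 to 1201138, NCBI gene 4586), from 23.1 ± 1.2 to 4.43 ± 0.16 FPKM (log2 difference −2.15 ± 0.10), and MUC5B (−1.77) were lower, as were the water channel AQP3, from 35.4 ± 1.7 to 7.88 ± 0.49 FPKM (−2.04), ADH1C (−2.02), FCGBP (−2.00) and S100P (−1.71). MUC5B-AS1 (−2.02) is antisense to MUC5B, and their reads cannot be told apart here. Higher were STC2, from 5.15 ± 0.19 to 16.3 ± 0.99 FPKM (1.49), the insulin-like growth factor-binding protein IGFBP7 (1.22), the orphan receptor NR4A1 (1.15), TRIB3 (1.04) and the securin PTTG1 (1.00). Of 35 G2/M genes 33 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 1.22e-24, and adjusted p = 0.0142 with an estimated correlation). One example was CCNB1 from 59.8 ± 2.2 to 107 ± 0.85 FPKM (0.83). Of 30 cholesterol synthesis genes 24 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 6.45e-14, and adjusted p = 0.00182 with an estimated correlation). Among these was INSIG1 (0.71). Of 10 alveolar and lung adenocarcinoma markers 7 fell and 1 rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 9.75e-07, and adjusted p = 0.0272 with an estimated correlation). Examples were the trefoil factor TFF1 (−1.06) and CEACAM6 (−1.01). Of the few markers of other cell types, 2 of 3 leukocyte and macrophage markers and 1 of 2 endothelial markers fell, and 1 of 3 fibroblast markers rose. Of 13 replication-dependent histones, measured in libraries enriched for polyadenylated RNA, 9 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.000639, and adjusted p = 0.0272 with an estimated correlation). A member was H2BC11 (0.91). Of 26 iron-handling genes 14 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.00278, and adjusted p = 0.0225 with an estimated correlation). Named members were HMOX1 (0.87) and SLC3A2 (0.64). Calls lost with an estimated correlation were those of S-phase genes (22 fell, 1 rose; adjusted p = 0.281), unfolded protein response genes (19 rose, 8 fell; adjusted p = 0.549), hypoxia genes (13 rose, 3 fell; adjusted p = 0.368), ribosomal protein genes (16 rose, 0 fell; adjusted p = 0.793) and mitochondrially encoded genes (7 fell, 2 rose; adjusted p = 0.604), the last 2 also under quantile normalization. Past the test were 4656 genes, 2259 higher and 2397 lower, with 40 at an absolute log2 difference of at least 1, of which 30 were lower.

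Interactions tested whether the exposure effect differed between genotypes. In iR, CDC42EP2, an effector of the CDC42 GTPase, rose more in the knockout (difference of log2 differences 0.87 ± 0.09, SE, n = 3 in each of 4 groups, adjusted p = 6.83e-06), as did AMOTL2 (0.65), and RND1 (−0.68), RASSF10 (−0.67), UBALD2 (−0.61) and RSRP1 (−0.61) changed the other way. The secreted factors shifted upward in the knockout relative to the wild type (4 of 38 higher, or 7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00248, and adjusted p = 0.0484 with an estimated correlation). One of these was CXCL1 (0.54). The cholesterol list shifted downward with 0 members past either adjustment (limma for single genes; median −0.08, camera adjusted p = 0.000186, and adjusted p = 0.0414 with an estimated correlation). With limma 65 of 12,086 genes passed, 33 higher and 32 lower, and 1177 had an unadjusted p under 0.05. The count fell to 30 without iR_WTA_EX replicate 1, to 43, 39 and 37 without iR_WTA_NE replicates 1, 2 and 3, and to 17 when only the compared groups were fitted. CXCL1 did not pass without iR_WTA_EX replicate 1, and AMOTL2, RND1 and RASSF10 did not pass with the compared groups only, nor UBALD2 with a replicate block. Passing with the preset correlation only were NF-kB targets, mitochondrially encoded genes (up) and unfolded protein response, immediate early, nuclear respiratory chain and ribosomal protein genes (down), at adjusted p = 0.116 to 0.729 with an estimated correlation. Quantile normalization ended the calls of the mitochondrially encoded, unfolded protein response and ribosomal lists.

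With D3, CCN2, a member of the secreted list, rose more in the knockout (1.12 ± 0.10, adjusted p = 2.15e-07). So did TGFB2-AS1 (1.49), which overlaps the antisense strand of the growth factor TGFB2 (0.54) and cannot be separated from it. The cell-cycle inhibitor CDKN2D (−1.24 ± 0.17, adjusted p = 8.3e-05), RND1 (−0.84) and the lipase PNPLA3 (−0.90), near 0 in the knockout, changed the other way. NR4A1 differed by 0.60. Secreted factors again shifted upward (4 higher, 0 lower, or 9 and 1 adjusted over the list alone; camera adjusted p = 0.00231, and adjusted p = 0.0475 with an estimated correlation), and cholesterol synthesis downward (2 lower, or 13 adjusted over the list alone; camera adjusted p = 1.61e-07, and adjusted p = 0.00954 with an estimated correlation). Among these was HSD17B7 (−0.41; not past with voom). The threshold was passed by 288 genes, 150 higher and 138 lower, against 125 and 172 with median-of-ratios scaling. The count was 170 without iR_KOA_D3_NE replicate 2, 189 without iR_WTA_D3_NE replicate 3, 504 without iR_WTA_D3_EX replicate 3 and 106 with the compared groups only. Nuclear respiratory chain and ribosomal protein genes (up) and lung markers (down) passed with the preset correlation only (adjusted p = 0.303 to 0.793 with an estimated correlation), and lung markers did not pass with median-of-ratios scaling.

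Between iR_KOA and KOA the exposure effect differed in 614 genes, 201 higher and 413 lower (292 and 363 with quantile normalization). HSPA6 rose less in iR_KOA than in KOA (−2.96 ± 0.22, adjusted p = 1.39e-09; not past with voom), and so did CLK1 (−2.00 ± 0.11), CCN1 (−1.54), the transcription factor CEBPD (−1.47), AMOTL2 (−1.46), CCN2 (−1.43) and BAG3 (−1.03). The arrestin-domain protein ARRDC3 (1.21), KLF10 (0.94) and NRIP1 (0.84) differed the other way. Of the secreted factors 5 of 38 were lower, CCN1 and CCN2 among them, or 7 adjusted over the list alone (camera adjusted p = 0.000625, and adjusted p = 0.0278 with an estimated correlation). Of 28 heat shock genes 13 were lower, or 22 adjusted over the list alone (camera adjusted p = 2.82e-17, and adjusted p = 0.0786 with an estimated correlation). Mitochondrially encoded genes (7 of 13 higher; adjusted p = 0.0748 with an estimated correlation) did not pass with quantile normalization, nor did nuclear respiratory chain genes (down, 0.622). Histones, immediate early and ribosomal protein genes (down) and NRF2 targets (up) also passed with the preset correlation only (0.068 to 0.6).

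The exposure effect differed with D3 in 202 genes of the wild type and 500 of the knockout. In the wild type KHDC4 (0.68) and BTG2 (0.89 ± 0.15, adjusted p = 0.00167), an antiproliferative p53 target, were relatively higher with D3, and SOCS3 (−1.10), BHLHE40 (−0.84) and GADD45B (−0.82) relatively lower. Of 36 p53 targets 6 were higher, or 9 adjusted over the list alone (camera adjusted p = 0.000334, and adjusted p = 0.0291 with an estimated correlation). In the knockout PDK4, a kinase that restrains pyruvate oxidation (0.78), and OSGIN1 (0.71) were relatively higher, and SOCS3 (−1.16 ± 0.12, adjusted p = 2.79e-06), JUN (−0.82), RND1 (−0.78) and KLF10 (−0.73) lower. Of 21 NF-kB targets 4 were lower, or 6 adjusted over the list alone (camera adjusted p = 0.000109, and adjusted p = 0.0198 with an estimated correlation). One example was CXCL1 (−0.77). The wild-type count was 91 higher and 111 lower (124 and 87 with median-of-ratios scaling) and was 88 without iR_WTA_NE replicate 2 and 128 without iR_WTA_D3_EX replicate 1. It was 506 without iR_WTA_D3_EX replicate 2, 101 without iR_WTA_D3_EX replicate 3, 117, 112 and 115 without iR_WTA_D3_NE replicates 1, 2 and 3, and 92 and 108 without iR_WTA_EX replicates 2 and 3. The knockout count (210 higher, 290 lower) was 263 and 319 without iR_KOA_D3_EX replicates 1 and 3, 315 and 265 without iR_KOA_D3_NE replicates 1 and 2, and 265, 245 and 910 without iR_KOA_NE replicates 1, 2 and 3. Lists that passed with the preset correlation only were, in the wild type, G2/M, heat shock, cholesterol and splicing genes (up) and NF-kB, immediate early and hypoxia genes (down), at adjusted p = 0.0564 to 0.713 with an estimated correlation. In the knockout they were p53, G2/M, histone, heat shock, splicing, nuclear respiratory chain and ribosomal genes (up) and hypoxia, mitochondrially encoded and clock genes (down), at 0.104 to 0.604. Quantile normalization ended the calls of heat shock genes in both, of cholesterol genes in the wild type, and of splicing, mitochondrially encoded and clock genes in the knockout.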

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

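The tests on heating, on misfolded protein, on chromosome 2, on segments of chromosomes, and on RSRP1 against scaling and against its neighbours were chosen only after the results were seen. The other tests were written before the data were examined.

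Each result in this paragraph is given because the test of the interaction found that the effect of exposure differed between 2 backgrounds. The number of such genes was 65 between genotypes in iR, 288 between genotypes in iR with D3, 614 between iR_KOA and KOA, 202 between iR_WTA_D3 and iR_WTA, and 500 between iR_KOA_D3 and iR_KOA. For RSRP1 the difference of log2 differences was −0.606 and −0.373 between genotypes without and with D3 and 0.385 between iR_KOA_D3 and iR_KOA. Secreted cytokines shifted by a median of 0.078 between genotypes in iR, 0.071 in iR with D3, and −0.104 between iR_KOA and KOA. Cholesterol synthesis genes shifted by −0.077 and −0.154 between genotypes without and with D3. The median was 0.067 for p53 targets between iR_WTA_D3 and iR_WTA and −0.178 for NF-kB targets between iR_KOA_D3 and iR_KOA.

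Heat shock genes were higher with exposure in all 5 backgrounds. Scaling between libraries was excluded, since the lowest median over 5 comparisons and 2 other scalings was 0.8. Heating of the exposed cells could explain the rise, and CIRBP and RBM3, which warming lowers, were lower in 10 of 10 tests, though RBM3 in KOA did not pass without KOA_EX replicate 1 (−0.108) or 2 (−0.128) or KOA_NE replicate 2 (−0.145) or 3 (−0.122). Misfolded protein without heating could explain it as well, and HSPA5, DNAJB9 and HERPUD1 were higher in 15 of 15 tests. CIRBP and RBM3 were chosen after their values were seen, so the count for heating restates known values and is not a test of heating. DNAJB9 and HERPUD1 were already known to pass in all 5 backgrounds, so their part of the other count restates that result. HSPA5 is given above as a rise in iR_WTA, so part of its count does so too. The tests do not separate the 2 explanations, and no temperature is given in the sources used here.

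The genotypes differed by at least 2 times in 600 genes in iR and 719 with D3. A difference in copy number between the lines is a candidate explanation for chromosome 2, whose median lay 0.389 or more above that of other genes. It is also one for chromosomes X, 15, 17, 14 and 16, whose smaller whole-chromosome medians lay outside the permuted ones. Part of chromosome X shifted more than chromosome 2: 4 of its windows had medians of 0.527 to 0.713 in iR, where those of chromosome 2 reached 0.489. However, shifts of up to 0.082 also appeared within one genotype. For most of the 596 placed 2-fold genes in iR a shift of their whole window was too small to be the whole cause. Of these genes 86.4 percent lay in windows within the permuted range, which also holds shifted windows. After the median of their own window, at most 0.713, was taken off, 79.9 percent stayed 2-fold. These medians lay below the log2 difference of 1 that defines 2-fold, so only genes close enough to 1 could drop out. The share therefore adds little to the size of the medians themselves. Medians of 40 genes cannot show a change in copy number of single genes or short segments, which was not tested. Scaling was excluded, with at least 583 such genes under 2 other scalings. The loss of RSRP1 itself cannot be told from other differences between the lines. The genotype difference with D3 and the iR difference in the knockout had a Spearman rho of −0.361. This covers only the 718 genes at least 2-fold between genotypes with D3, without RSRP1, and genes are not independent replicates. Moreover, iR differs between libraries that are all knockout.

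RSRP1 was higher with exposure in both wild-type backgrounds. Scaling was excluded, as the lowest log2 difference under 2 other scalings was 0.377. The higher of 2 medians of the neighbouring genes was 0.007. This cannot decide whether reads from a neighbour contributed, since a rise of a single neighbour need not move the median. A biological response to the exposure remains possible and may follow from the stress that raises the heat shock genes, which was not tested.

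With 3 against 3 libraries there are only 10 ways to split 6 samples, too few for a test. In each of the 10 pairwise comparisons only 1 split, the real one, had as many changed genes. Every other split mixes libraries of both real groups on each side. A strong real difference then widens the spread within each side and largely cancels between the sides. Low counts in the other splits therefore follow from such a difference and do not give a rate of false calls. The highest count of any other split was 1 in KOA against 5020 for the real one, 3 in iR_KOA against 4272, 0 in iR_KOA_D3 against 5455, 1 in iR_WTA against 3462 and 1 in iR_WTA_D3 against 5055. For genotype it was 0 against 7895 and 0 against 8352, for D3 1 against 5880 in the wild type and 0 against 6485 in the knockout, and for iR 0 against 4656.

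For the interactions, 100 draws of the 12 samples' deviations from the additive model were made. As many changed genes as in the real order were found in 2 draws between genotypes in iR, 1 with D3, 1 for iR in the knockout, 2 for D3 in the wild type and 4 for D3 in the knockout, each counting the real order. The highest count of another draw was 683 against 65, 1 against 288, 184 against 614, 710 against 202 and 727 against 500. Draws with several times the real count point to a structure of the samples, whose nature was not tested. Some draws exceeded the real counts of 65, 202 and 500.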

How the results depend on the processing

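Counts of changed genes stayed within 1.5 times under median-of-ratios scaling, quantile normalization, no filter and voom, which was added after seeing the data, in all 15 comparisons. RSRP1 kept its direction and its side of the threshold except as given here, and depth was close to even. With a filter of mean FPKM at least 5, fewer genes are tested, and exposure counts were 3082 in KOA, 2836 in iR_KOA, 3378 in iR_KOA_D3, 2249 in iR_WTA and 3095 in iR_WTA_D3. Genotype counts were 4991 and 5220 with D3, iR in the knockout 3098, and interactions 37 and 159 between genotypes without and with D3, 367 for iR and 127 for D3 in the wild type. A floor of 1 on the absolute log2 difference left, by construction, 109, 34, 58, 33 and 53 genes for exposure in the same order, 600 and 719 for genotype, 82 and 268 for D3 in the wild type and the knockout, 40 for iR, and 0, 5, 15, 4 and 1 for the interactions between genotypes, between genotypes with D3, for iR, and for D3 in the wild type and the knockout.

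When only the compared groups were fitted, with fewer samples, counts were 2131 for exposure in iR_KOA, 17 and 106 for the genotype interactions without and with D3, and 52 and 158 for the D3 interactions in the wild type and the knockout. The RSRP1 interaction with D3 was −0.373 there and no longer past the threshold (adjusted p over all its alternatives 0.00704 to 0.0691). The genotype interaction in iR held 40 genes with a pseudocount of 0.1 and 31 with the replicate number as a block. Of 15 same-numbered pairs 7 correlated above 0.1 (−0.239 to 0.306) and 11 correlated best with their own number, a hint of pairing from the data that the labels do not give. In iR_KOA_D3 all 3 pairs lay above it (0.115 to 0.168), and the block left 5390 genes there. With an estimated correlation 38 list tests passed, against 136. RSRP1 with exposure in iR_KOA_D3 passed at 0.158 with median-of-ratios scaling and 0.168 with quantile normalization. Direction reversed for RRAD between genotypes in iR with voom (−1.038), for BMF in the D3 interaction of the wild type with voom (0.382) and for ND4L between genotypes in iR with quantile normalization (−0.046). For all these the cause was not tested.

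Leaving out each library gave 30 to 74 genes for the genotype interaction in iR (lowest without iR_WTA_EX replicate 1), 170 to 504 with D3 (without iR_KOA_D3_NE replicate 2 and iR_WTA_D3_EX replicate 3), 88 to 506 for D3 in the wild type (without iR_WTA_NE replicate 2 and iR_WTA_D3_EX replicate 2) and 245 to 910 for D3 in the knockout (without iR_KOA_NE replicates 2 and 3). The median squared difference between replicates, relative to counting reads alone, was highest for iR_WTA_D3_EX replicates 2 and 3 (11.2). For iR_KOA_NE replicate 3 it was 6.04 and 5.59 against replicates 1 and 2, and 2.41 between those. Whether this caused the range of counts was not tested. RSRP1 ranged from −0.179 (without KOA_NE replicate 1) to −0.056 with exposure in KOA and from 0.101 to 0.171 (without iR_KOA_D3_EX replicate 2) in iR_KOA_D3.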

Other observations

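The share of FPKM held by mitochondrially encoded genes ranged over the groups from 20.9 ± 0.52 percent (SD, n = 3) in exposed iR_WTA to 29.4 ± 1.2 percent in unexposed iR_KOA_D3. In exposed iR_KOA it was 25.8 ± 2.2 percent and in exposed iR_KOA_D3 28.1 ± 0.99 percent.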
